A study of Mus musculus with 9 samples.

How the data were processed

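Bulk RNA sequencing was deposited for whole ganglia of C57BL/6 mice: jugular and nodose ganglia (JNC), dorsal root ganglia (DRG) and trigeminal ganglia (TG), with 3 libraries per group. Per the labels, RNA was extracted with a column kit for small samples and made into standard Illumina libraries, and the strand protocol is not stated. The labels do not give sex, age or spinal level, or say whether libraries came from separate animals. The deposited files are 3 gene tables, 1 per pair of ganglia, each holding the 6 libraries of that pair and 23936 genes.

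The expected counts, deposited as raw fragments per gene and library, came from the authors' Cuffdiff run per the file headers and were not normalized. Between 1.90% and 2.00% of them lay further than 1e-09 from a whole number, and they were rounded. The FPKM values, deposited by the authors in the same tables, were made by Cuffdiff within each pair of ganglia after scaling the libraries of that table to each other. Per the submitters' processing notes, TopHat, Cufflinks and Cuffdiff were used with the mm9 genome build, and no versions or parameters are given. A library held almost the same counts in both tables that contain it. Replicates numbered 0 to 2 in the files are named 1 to 3. Genes whose status in a table was not OK were left out, 23 for JNC and DRG, 29 for DRG and TG and 29 for JNC and TG. No genome coordinates were used for any value.

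Genes with FPKM of at least 1 in at least 3 of the 6 libraries of a table were tested. Each table was fitted alone with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The design written before the data were examined named limma on log2(FPKM + 1) first and this count model if the tables held counts, which they did. The SE of a log2 fold change was taken as its size divided by the square root of F and is approximate. Levels are FPKM as mean ± SD. CPM were computed from the counts and the library totals. With 3 libraries against 3, the smallest exact permutation p is 0.1.

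Folds of genes close to 0 were computed from fragments pooled over a group, with a floor of 3. Where a group held 0 fragments the fold is a lower bound, and where it held 1 to 3 fragments a 95% counting interval is given. These intervals cover counting error only. Libraries of a group differed by more than counting noise, with chi-square per degree of freedom between 6.72 and 30.3. The fitted log2 fold changes of such genes are no bounds.

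Genes to name were set by a rule before the data were examined. It took the 5 genes with the largest log2 fold change each way among those past the threshold whose libraries did not overlap and whose level reached FPKM 5 in a group. It added up to 4 members of each of 31 fixed gene lists and 9 genes always given, among them P2rx2, Trpv1, Trpa1, Trpm8, Tac1, Calca, Prdm12 and Atf3. A few results that the rule names are not reported here. The lists cover sensory neuron classes, Hox genes, channels, receptors, peptides, injury and immediate early genes, and markers of other cells and nearby tissues. The list symbols Accn1, Accn2, Accn3, Tafa3, Hbb-bt and Ahsp had no match in the tables. Reads of close paralogs (Mrgpr genes, globins, Calca and Calcb) are uncertain. Lists with at least 3 tested members were tested with camera and fry in limma 3.58.1, with Benjamini-Hochberg adjustment over lists. The preset camera correlation of 0.01 was used, and p with a correlation estimated from the data is given beside each call.

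The overlap of the 2 comparisons that share JNC was set beside independent lists and beside 20 simulations of unchanged groups sharing those libraries. Alternatives planned before the data were examined were other filters, upper-quartile and quantile scaling, centring on pan-neuronal genes, library weights, no intensity trend, pseudocounts of 0.1 and 0.5, stricter thresholds, a replicate block and leaving out each library. Limma on log2(FPKM + 1), named in the design, was kept as an alternative once the tables were seen to hold counts. Chosen after seeing the data were DESeq2 1.42.0, a fit of all 9 libraries, and leaving out libraries for the single genes. The test was checked on simulated data with the means, dispersions and depths of each table, where 66%, 73% and 61% of genes changed 1.5-fold were recovered for JNC and DRG, DRG and TG, and JNC and TG. Of genes changed 3-fold, 98% were recovered in each, with 15, 26 and 16 false calls. Only 100 genes were changed at each fold. Most genes were thus unchanged, unlike in the real tables, and the check does not cover the scaling or the false calls there. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for tables, tests and figures.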

Results

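Bulk RNA sequencing profiled whole sensory ganglia of C57BL/6 mice, an inbred laboratory strain, at 3 body levels. The vagal ganglia, the fused jugular and nodose ganglia of the vagus nerve (JNC), hold the sensory neurons of the airways, heart and gut. Dorsal root ganglia (DRG) hold the somatosensory neurons of trunk and limbs, and trigeminal ganglia (TG) those of the face and head. Each group had 3 libraries. The files assigned to genes 17384939, 27405144 and 21368764 fragments in the JNC libraries, 24485145, 22696427 and 29982177 in the DRG libraries and 24692258, 24523993 and 34644408 in the TG libraries, in the order of replicates 1 to 3. Correlations of log2 expression between libraries of 1 group ran from 0.995 to 0.998. Between groups they ran from 0.975 to 0.980 for JNC and DRG, from 0.973 to 0.981 for DRG and TG, and from 0.961 to 0.967 for JNC and TG. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure only the spread between these samples.

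Levels below are FPKM, as mean ± SD of n = 3 libraries per group. CPM are fragments of a gene scaled to the library total. Log2 fold changes are the first named ganglion minus the second, ± an approximate SE, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. "Higher" is used of genes whose adjusted p passed the threshold of 0.05, and counts of list members follow it. A gene near 0 in 1 ganglion could be tested only through the libraries of the other. Counts of tested members thus lean toward the ganglion that expresses a list. Pan-neuronal centring, an alternative scaling, sets the libraries by the median level of the pan-neuronal genes. After this centring the median log2 fold change of those genes was 0.42 for JNC and DRG and 0.51 for JNC and TG. For DRG and TG it was -0.06, so the centring did not give equal neuron content throughout. Member counts under it are given where a count differed by 2 or more, and camera p are without it unless stated. A fold given with a counting interval is a ratio of fragment counts, and the interval covers counting error only. Folds against a group with 0 fragments are lower bounds set by a floor of 3 fragments over the group. Values from different pairs of ganglia come from tables normalized separately.

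The first comparison asked which transcripts set vagal sensory ganglia apart from dorsal root ganglia. Genes of placode-derived visceral sensory neurons were mostly higher in JNC than in DRG. P2rx2, a subunit of ATP-gated channels, had FPKM 90.4 ± 5.27 in JNC and 1.24 ± 0.178 in DRG (log2 fold change 6.18 ± 0.11). In the other direction DRG carried higher levels of posterior Hox genes and of low-threshold mechanoreceptor markers. With an estimated correlation camera called 2 lists, the placodal and the mechanoreceptor markers. Hoxa10 reached 0.0272 ± 0.00607 in JNC and 15.2 ± 1.67 in DRG (-9.00 ± 0.22), and Calca, which encodes calcitonin gene-related peptide, 239.9 ± 99.6 in JNC and 1336 ± 124 in DRG (-2.47 ± 0.25).

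Of 17 tested placodal vagal neuron markers, 16 were higher in JNC, and 1, the angiotensin receptor gene Agtr1a (-0.81 ± 0.21, adjusted p 0.159 with pan-neuronal centring), was higher in DRG (camera adjusted p 8.63e-67, adjusted p = 0.00235 with an estimated correlation). Phox2a, a homeobox factor, was at least 129-fold higher, at 3.30 ± 0.740 in JNC and 0 ± 0 in DRG. Vip, encoding vasoactive intestinal peptide, had FPKM 17.5 ± 5.06 in JNC and 0.0362 ± 0.00982 in DRG (8.75 ± 0.39). Uts2b, encoding a urotensin peptide, had 34.8 ± 8.82 in JNC and 0.438 ± 0.279 in DRG (6.21 ± 0.33, and 6.88 without DRG replicate 3). Among visceral mediator receptors, 13 of 26 were higher in JNC and 9 in DRG (15 in JNC and 6 in DRG with pan-neuronal centring, camera adjusted p 8.83e-05, adjusted p = 0.0914 with an estimated correlation). They included Glp1r, the receptor for glucagon-like peptide 1, at 26.6 ± 6.16 in JNC and 0.398 ± 0.163 in DRG (6.03 ± 0.26), and the proton-sensing receptor Gpr65 at 26.6 ± 0.719 in JNC and 0.416 ± 0.0191 in DRG (6.00 ± 0.11). P2X, serotonin, nicotinic and acid-sensing channels went both ways, with 9 of 19 higher in JNC and 9 in DRG (10 in JNC and 5 in DRG with pan-neuronal centring, camera adjusted p 3.40e-08, adjusted p = 0.0914 with an estimated correlation). The nicotinic receptor subunits Chrna3 and Chrnb4 had log2 fold changes of 4.54 ± 0.09 and 3.76 ± 0.12. Neuropeptide genes were divided, 6 of 14 each way (camera adjusted p 0.400, median log2 fold change -0.02, 0.49 after pan-neuronal centring), with Cartpt at 158 ± 3.11 in JNC and 10.4 ± 2.13 in DRG (3.92 ± 0.12).

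Neural crest somatosensory neuron markers were higher in DRG for 17 of 19 members and higher in JNC for 1 (camera adjusted p 3.16e-12, adjusted p = 0.135 with an estimated correlation). Il31ra, a subunit of the receptor for the itch cytokine interleukin 31, had FPKM 0.801 ± 0.309 in JNC and 13.2 ± 2.46 in DRG (-3.99 ± 0.22), and Nppb, an itch-related natriuretic peptide, 0.759 ± 0.510 in JNC and 11.4 ± 2.48 in DRG (-3.82 ± 0.36). Prdm12, a transcription factor of nociceptor development, had 9.38 ± 3.52 in JNC and 53.5 ± 2.29 in DRG (-2.50 ± 0.19). Nociceptor channels and peptides were higher in DRG for 10 of 15 and higher in JNC for 5 (5 in JNC and 7 in DRG with pan-neuronal centring, camera adjusted p 0.0649, but 0.0167 without JNC replicate 1, 0.0342 without DRG replicate 1, 0.0153 without DRG replicate 3 and 9.33e-04 with pan-neuronal centring). Calcb and Tac1 were lower in JNC, as was Calca, with Calcb at -2.59 ± 0.19 and Tac1, encoding substance P, at -1.38 ± 0.14 with FPKM 98.7 ± 20.9 in JNC and 258 ± 37.2 in DRG. Both irritant receptors on that list were higher in JNC. Trpa1, the channel gated by electrophilic irritants, had 58.5 ± 6.39 in JNC and 16.3 ± 1.58 in DRG (1.86 ± 0.10), and Trpv1, the capsaicin receptor, 18.5 ± 1.20 in JNC and 11.4 ± 1.06 in DRG (0.70 ± 0.09). Trpm8, the menthol and cold receptor, had 3.59 ± 1.69 in JNC and 11.6 ± 3.07 in DRG (-1.67 ± 0.30). Low-threshold mechanoreceptor and proprioceptor markers were higher in DRG for 13 of 16 and higher in JNC for 3 (3 in JNC and 11 in DRG with pan-neuronal centring, camera adjusted p 3.11e-08, adjusted p = 0.0470 with an estimated correlation). Slc17a8, a vesicular glutamate transporter, had log2 fold change -3.85 ± 0.13, and Pvalb, a calcium-binding protein of proprioceptors, -3.80 ± 0.35 (-4.63 without JNC replicate 3).

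The posterior Hox genes, paralogs 6 to 13, were higher in DRG for 12 of 13 members, and 1, Hoxb6 (2.48 ± 0.14), was higher in JNC (camera adjusted p 2.20e-27, adjusted p = 0.0914 with an estimated correlation). Hoxc10 was at least 205-fold higher in DRG, at FPKM 0 ± 0 in JNC and 5.16 ± 0.111 in DRG. Hoxa9 was higher by 879-fold, with a counting interval from 243 to 7266, and Hoxa7 by 549-fold, with a counting interval from 152 to 4537, its fitted log2 fold change moving from -8.93 to -11.61 without JNC replicate 2. Mira is annotated as a separate noncoding RNA in RefSeq but is covered by the end of Hoxa7 in GENCODE, so its reads are uncertain, and it had 0.180 ± 0.0400 in JNC and 32.9 ± 4.70 in DRG (-7.41 ± 0.24). Of the anterior Hox genes, paralogs 1 to 5, 6 of 10 were higher in JNC and 2 higher in DRG (camera adjusted p 3.04e-04, adjusted p = 0.0914 with an estimated correlation). Hoxb5 reached 210.3 ± 23.8 in JNC and 18.4 ± 2.95 in DRG (3.53 ± 0.13) and Hoxb4 18.0 ± 1.18 in JNC and 1.24 ± 0.264 in DRG (3.86 ± 0.14), while Hoxa5 was higher in DRG (-3.87 ± 0.29). Sensory neuron and cranial transcription factors went both ways, 6 higher in JNC, 7 higher in DRG and 5 not passing (9 in JNC and 5 in DRG with pan-neuronal centring, camera adjusted p 0.670, median log2 fold change -0.09, 0.40 after pan-neuronal centring). Eya1, a cofactor of cranial placode development, had 33.7 ± 2.44 in JNC and 0.924 ± 0.544 in DRG (5.15 ± 0.29), and Pou4f2, a POU-domain factor, 0.573 ± 0.142 in JNC and 9.72 ± 0.458 in DRG (-4.09 ± 0.15).

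Potassium channel genes were higher in DRG for 22 of 32 and higher in JNC for 7 (10 in JNC and 18 in DRG with pan-neuronal centring, camera adjusted p 8.73e-07, adjusted p = 0.158 with an estimated correlation). Kcnip1 and Kcnip2, which encode subunits that bind Kv4 channels, had log2 fold changes of -3.12 ± 0.17 and -2.76 ± 0.13. Sodium channel genes were 5 higher in JNC and 9 in DRG (5 in JNC and 6 in DRG with pan-neuronal centring, camera adjusted p 0.450, but 0.00373 with a filter of FPKM 5), with Scn3a at 2.35 ± 0.10 and the auxiliary subunit Scn4b at -2.17 ± 0.13. TRP channels (4 higher in JNC, 6 higher in DRG and 5 not passing, 9 in JNC and 4 in DRG with pan-neuronal centring, camera adjusted p 0.860, median log2 fold change -0.05, 0.47 after pan-neuronal centring) included Trpc4 at 2.31 ± 0.13. Cold-sensing neuron markers (2 higher in JNC, 2 higher in DRG and 2 not passing, camera adjusted p 0.820, median log2 fold change -0.26, 0.24 after pan-neuronal centring) included Kcnk9 at 4.27 ± 0.24 and Cdh8 at -2.42 ± 0.13. Cytokine and neurotrophic factor receptors and ligands were 6 higher in JNC, 13 higher in DRG and 7 not passing (10 in JNC and 8 in DRG with pan-neuronal centring, camera adjusted p 0.0156, adjusted p = 0.114 with an estimated correlation, median log2 fold change -0.29, 0.23 after pan-neuronal centring). The receptor tyrosine kinase Ntrk3 had -2.30 ± 0.15.

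Nerve injury response genes, measured here in ganglia with no injury named in the labels, were 11 higher in JNC, 4 higher in DRG and 6 not passing (13 in JNC and 1 in DRG with pan-neuronal centring, camera adjusted p 6.59e-04, adjusted p = 0.0914 with an estimated correlation). Their 3 members with the largest differences were Vip, given above, Cckbr, a cholecystokinin receptor (5.23 ± 0.34, and 6.05 without DRG replicate 3), and Arg1, arginase 1 (4.48 ± 0.33, and 5.09 without DRG replicate 1). Vip is also on the placodal and neuropeptide lists, and Cckbr on the visceral mediator receptor list. Calls of the injury list are thus not independent of those lists and do not show an injured state. Atf3, a transcription factor induced by axon injury, had FPKM 3.76 ± 0.785 in JNC and 2.31 ± 0.514 in DRG (0.70 ± 0.21, adjusted p 0.0179). Its adjusted p was 0.0699 without JNC replicate 3 and 0.0733 without DRG replicate 1. Of 13 immediate early genes 5 were higher in JNC and 0 in DRG (9 in JNC and 0 in DRG with pan-neuronal centring, camera adjusted p 0.450), led by Zfp36 (1.35 ± 0.15).

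Markers of other cells were measured beside these groups. Pan-neuronal genes were 4 higher in JNC, 8 higher in DRG and 5 not passing (9 in JNC and 4 in DRG with pan-neuronal centring, 6 in JNC and 5 in DRG with quantile normalization, camera adjusted p 0.338). The neurofilament gene Nefh had -2.36 ± 0.14 and Gap43, a growth cone protein, 1.34 ± 0.06. Satellite glia markers were 0 higher in JNC, 2 higher in DRG and 10 not passing (9 in JNC and 1 in DRG with pan-neuronal centring, camera adjusted p 0.507, median log2 fold change -0.04, 0.47 after pan-neuronal centring). S100b had -0.97 ± 0.07. Myelinating Schwann cell markers were 0 higher in JNC, 10 higher in DRG and 5 not passing (1 in JNC and 5 in DRG with pan-neuronal centring, camera adjusted p 0.0206, adjusted p = 0.764 with an estimated correlation, and camera adjusted p 0.0613 without JNC replicate 3 and 0.0546 with a filter of FPKM 5), with Pmp2 at -3.35 ± 0.39 and Prx at -0.97 ± 0.21. Neutrophil and bone marrow markers were higher in DRG for all 5 tested, of 9 listed (camera adjusted p 0.00501, adjusted p = 0.299 with an estimated correlation). Ngp had -3.39 ± 0.44 and Camp had -3.07 ± 0.49. Cartilage and bone markers were likewise higher in DRG for all 3 (camera adjusted p 0.00154, adjusted p = 0.108 with an estimated correlation). Chad had -5.11 ± 0.37 and Comp had -2.56 ± 0.25. Fibroblast and meningeal markers were 2 higher in JNC, 2 higher in DRG and 9 not passing (7 in JNC and 2 in DRG with pan-neuronal centring, camera adjusted p 0.852, but 0.0340 without DRG replicate 2 and 0.0244 with pan-neuronal centring), with Igf2 at -3.96 ± 0.42 and Ptgds at -4.95 ± 0.68 (-4.13 without DRG replicate 3). Sympathetic neuron and chromaffin markers were 3 higher in JNC, 3 higher in DRG and 0 not passing (3 in JNC and 1 in DRG with pan-neuronal centring, camera adjusted p 0.00714, adjusted p = 0.114 with an estimated correlation). Dbh, dopamine beta-hydroxylase, had FPKM 17.8 ± 8.41 in JNC and 0.0422 ± 0.0129 in DRG (8.68 ± 0.55), and Ddc, aromatic amino acid decarboxylase, 28.1 ± 1.37 in JNC and 0.640 ± 0.153 in DRG (5.49 ± 0.14).

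In all, 5817 of 12916 tested genes (45.0%) differed between JNC and DRG by edgeR's quasi-likelihood test, 2938 higher in JNC and 2879 higher in DRG. At least a 2-fold difference was reached by 680 and 731 of them. Besides Vip and Dbh, large differences toward JNC were those of Rprml (at least 132-fold higher, at 5.51 ± 0.979 in JNC and 0 ± 0 in DRG) and Myl1, a myosin light chain (41.2 ± 4.25 in JNC and 0.0893 ± 0.105 in DRG, log2 fold change 8.73 ± 0.29, and 10.11 without DRG replicate 3). All 3 libraries of 1 group lay above the 3 of the other for 7118 of the tested genes (55.1%, against 10% by chance). The split depended on the scaling. Centring each library on the median level of the 17 pan-neuronal genes shifted the median gene by 0.51 and gave 7927 genes higher in JNC and 785 higher in DRG. The median log2 fold change of the 17 genes went from -0.10 to 0.42, so this is not the split at equal neuron content. With a filter of FPKM 5 the neutrophil and the cartilage and bone lists kept under 3 members. With limma on log2(FPKM + 0.1), 6 lists lost their camera calls: the anterior Hox genes (adjusted p 0.0766), the P2X to acid-sensing channels (0.463), the visceral mediator receptors (0.208), the cytokine and neurotrophic list (0.0766), the injury genes (0.0766) and the sympathetic markers (0.479). Apart from Atf3, adjusted p of the genes named for this comparison ran from 2.47e-10 for P2rx2 to 0.00914 for Agtr1a by edgeR's quasi-likelihood test, and for each gene named all libraries of the higher group lay above those of the other. Agtr1a and Hoxb6 were named after their values were seen.

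**Figure D1:**
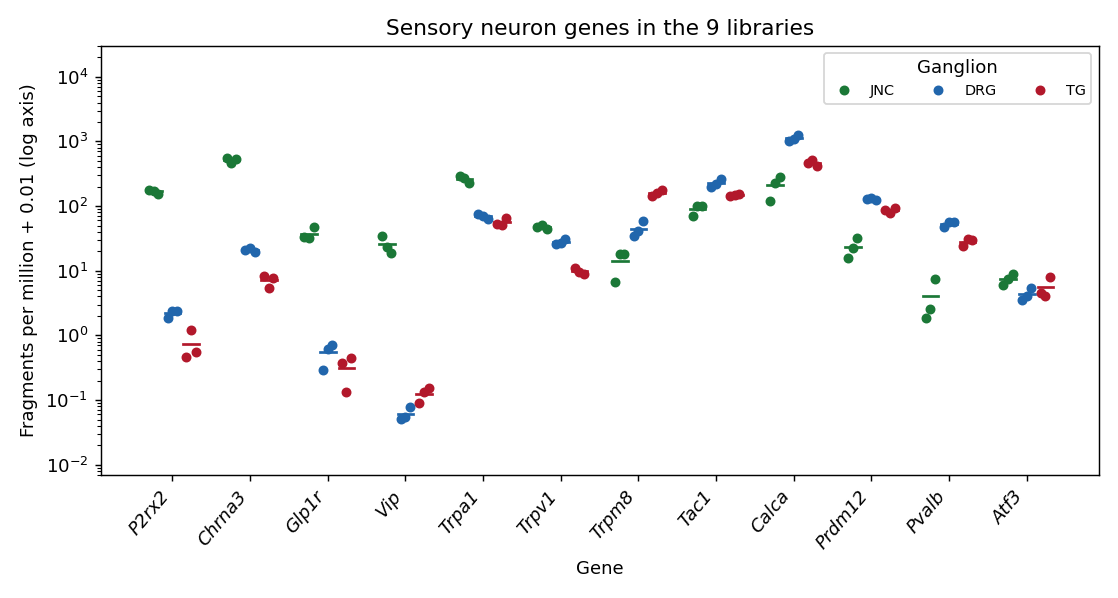
Sensory neuron genes in each library, as CPM plus 0.01 on a log axis, computed from the deposited fragment counts. Points are libraries, coloured by ganglion, and the short lines are means of n = 3. P2rx2 lay between 154 and 178 CPM in the JNC libraries and at or under 2.40 in the DRG and TG libraries, while Trpm8 was lowest in JNC and highest in TG.

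The second comparison set the 2 somatosensory ganglia against each other. All tested Hox genes and neural crest somatosensory neuron markers were higher in DRG, as were 11 of 17 pan-neuronal genes. TG carried higher levels of Trpm8, of glial and myelin genes, and of transcripts typical of the pituitary and of central glia. Camera with an estimated correlation called 0 lists for this pair. Hoxb5 had FPKM 18.3 ± 2.98 in DRG and 0.126 ± 0.0441 in TG (log2 fold change 7.14 ± 0.22), Trpm8 11.5 ± 3.02 in DRG and 40.9 ± 5.79 in TG (-1.84 ± 0.16), and Ugt8a, an enzyme of myelin lipid synthesis, 15.8 ± 3.98 in DRG and 145 ± 22.9 in TG (-3.22 ± 0.18). Prl, encoding the pituitary hormone prolactin, had 1.75 ± 0.588 in DRG and 1448 ± 1098 in TG (-9.71 ± 0.69, and -8.96 without TG replicate 3).

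All 13 tested Hox paralogs 6 to 13 and all 6 tested paralogs 1 to 5, of 24 and 15 listed, were higher in DRG (camera adjusted p 1.22e-31, adjusted p = 0.112 with an estimated correlation, and camera adjusted p 9.05e-09, adjusted p = 0.101 with an estimated correlation, respectively). Members near 0 in TG could pass the filter only through the DRG libraries, so the filter partly set the direction of these counts. With pan-neuronal centring 5 of paralogs 1 to 5 were higher in DRG and 1 in TG. That was Hoxd1, named after its values were seen, which stood at 14.0 ± 0.482 in DRG and 11.4 ± 0.816 in TG (0.27 ± 0.09, and -0.28 with that centring). Its adjusted p was 0.0518 and 0.0646 without DRG replicate 1 or 2, 0.0698 without TG replicate 2 and 0.149 with all 9 libraries in 1 fit. Hoxa7 was at least 463-fold higher, at 8.96 ± 0.111 in DRG and 0 ± 0 in TG, and Hoxc10 at least 259-fold, at 5.13 ± 0.120 in DRG and 0 ± 0 in TG. Hoxc4 was at least 101-fold higher, at 1.92 ± 0.307 in DRG and 0 ± 0 in TG. Hoxa10 had log2 fold change 8.33 ± 0.29 (9.48 without TG replicate 3). Hoxa9 was higher by 2227-fold, with a counting interval from 399 to 88001, and its fitted log2 fold change of 10.65 became 12.50 without TG replicate 2 and 10.06 without TG replicate 3. Mira, uncertain for the reason given above, was higher by 568-fold, with a counting interval from 194 to 2758, and its fitted 8.99 became 12.03 without TG replicate 3. Sensory neuron and cranial transcription factors were 8 higher in DRG, 7 higher in TG and 5 not passing (5 in DRG and 13 in TG with pan-neuronal centring, camera adjusted p 0.992). Onecut3 had -3.95 ± 0.22, Eya1 -2.50 ± 0.33, and Tlx3, a homeobox factor of sensory neurons, 2.33 ± 0.22.

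Neural crest somatosensory neuron markers were higher in DRG for all 19 members (15 in DRG and 0 in TG with pan-neuronal centring, camera adjusted p 4.68e-11, adjusted p = 0.141 with an estimated correlation). Mrgprd, a receptor of non-peptidergic nociceptors, had FPKM 62.1 ± 8.81 in DRG and 13.7 ± 0.821 in TG (2.16 ± 0.10), and Mrgpra3, a chloroquine receptor of itch neurons, 21.7 ± 7.55 in DRG and 3.26 ± 1.02 in TG (2.72 ± 0.28). Both belong to a family of close paralogs, so their counts are uncertain. Nppb had 2.42 ± 0.24 and Gfra2, a neurturin receptor, 2.07 ± 0.09. Nociceptor channels and peptides were 13 higher in DRG, 1 higher in TG and 1 not passing (8 in DRG and 3 in TG with pan-neuronal centring, camera adjusted p 8.26e-06, adjusted p = 0.141 with an estimated correlation). Calcb had 199 ± 32.5 in DRG and 36.6 ± 3.95 in TG (2.42 ± 0.12), Calca 1329.5 ± 120.4 in DRG and 546 ± 51.1 in TG (1.26 ± 0.10) and Trpv1 11.4 ± 1.03 in DRG and 3.91 ± 0.318 in TG (1.52 ± 0.12). The sodium channels of nociceptors, Scn11a and Scn10a, had 1.62 ± 0.11 and 1.11 ± 0.11, while the sodium channel list as a whole was 4 higher in DRG, 3 higher in TG and 6 not passing (2 in DRG and 9 in TG with pan-neuronal centring, camera adjusted p 0.521). Tac1 (257 ± 36.5 in DRG and 167 ± 9.01 in TG, 0.60 ± 0.10) and Prdm12 (53.2 ± 2.45 in DRG and 35.2 ± 4.42 in TG, 0.57 ± 0.09) were higher in DRG, but with pan-neuronal centring their adjusted p was 0.724 and 0.822. Trpa1 had 16.2 ± 1.62 in DRG and 12.97 ± 2.21 in TG (0.30 ± 0.11, adjusted p 0.0359). That call ended without DRG replicate 1 or 2 or TG replicate 1 or 2 (adjusted p 0.117, 0.0788, 0.106 and 0.136). It also ended with limma on log2(FPKM + 1) (0.0519, and 0.0599 without trend), with 0.1 added (0.0533) and with 0.5 added (0.0524), and the sign turned with pan-neuronal centring (-0.25). Beside these neuron genes, the pan-neuronal genes themselves were 11 higher in DRG, 2 higher in TG and 4 not passing (camera adjusted p 0.0136, adjusted p = 0.415 with an estimated correlation). With pan-neuronal centring 5 were higher in DRG and 7 in TG (camera adjusted p 0.153), but this list sets that centring, so these counts are no independent check. Uchl1 had 1.57 ± 0.08 and Tubb3 had 1.14 ± 0.08.

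Low-threshold mechanoreceptor and proprioceptor markers were 13 higher in DRG, 1 higher in TG and 2 not passing (8 in DRG and 5 in TG with pan-neuronal centring, camera adjusted p 1.22e-04, adjusted p = 0.112 with an estimated correlation, median log2 fold change 0.80, 0.24 after pan-neuronal centring). Th, the tyrosine hydroxylase that marks a class of C-fibre touch receptors, had FPKM 50.5 ± 5.88 in DRG and 2.80 ± 0.159 in TG (4.15 ± 0.11), and Calb1 was higher in TG (-1.40 ± 0.13). Cold-sensing neuron markers were 0 higher in DRG, 3 higher in TG and 2 not passing (0 in DRG and 5 in TG with pan-neuronal centring, camera adjusted p 0.0263, adjusted p = 0.246 with an estimated correlation, and 0.0518 with limma on log2(FPKM + 0.1) and 0.0783 with pan-neuronal centring, median log2 fold change -1.34, -1.91 after pan-neuronal centring). Besides Trpm8 the orphan receptor gene Gpr26 (-1.85 ± 0.16) and Foxp2 (-1.34 ± 0.21) were higher in TG. Potassium channels were 20 higher in DRG, 9 higher in TG and 3 not passing (14 in DRG and 14 in TG with pan-neuronal centring, camera adjusted p 0.00271, adjusted p = 0.373 with an estimated correlation, median log2 fold change 0.66, 0.11 after pan-neuronal centring). Kcnk12 had 4.24 ± 0.39 and Kcnip2 had 2.42 ± 0.11. Neuropeptides were 10 higher in DRG, 2 higher in TG and 1 not passing (8 in DRG and 3 in TG with pan-neuronal centring, camera adjusted p 6.33e-04, adjusted p = 0.246 with an estimated correlation), with Pomc, a pituitary prohormone, higher in TG at 0.642 ± 0.155 in DRG and 23.5 ± 14.4 in TG (-5.22 ± 0.53). Visceral mediator receptors were 14 higher in DRG, 4 higher in TG and 3 not passing (8 in DRG and 7 in TG with pan-neuronal centring, camera adjusted p 0.106, but 0.0391 with limma on log2(FPKM + 0.1) and 0.0257 with pan-neuronal centring), with the oxytocin receptor gene Oxtr at 0.491 ± 0.128 in DRG and 6.50 ± 0.650 in TG (-3.73 ± 0.17). Placodal vagal markers were 5 higher in DRG, 4 higher in TG and 1 not passing (camera adjusted p 0.817, median log2 fold change 0.31, -0.24 after pan-neuronal centring), and P2rx2 was low in both at 1.24 ± 0.176 in DRG and 0.443 ± 0.268 in TG (1.60 ± 0.33). TRP channels were 8 higher in DRG, 4 higher in TG and 3 not passing (6 in DRG and 8 in TG with pan-neuronal centring, camera adjusted p 0.347, median log2 fold change 0.30, -0.25 after pan-neuronal centring). Trpv2 had 1.66 ± 0.08. The P2X, serotonin, nicotinic and acid-sensing channels were 9 higher in DRG, 4 higher in TG and 5 not passing (6 in DRG and 9 in TG with pan-neuronal centring, camera adjusted p 0.0596, but 0.0401 without DRG replicate 3, median log2 fold change 0.30, -0.26 after pan-neuronal centring). Chrna4 had 2.09 ± 0.13. Nerve injury response genes were 7 higher in DRG, 5 higher in TG and 7 not passing (4 in DRG and 10 in TG with pan-neuronal centring, camera adjusted p 0.562, median log2 fold change 0.11, -0.45 after pan-neuronal centring). Gal, encoding galanin, had 1.81 ± 0.18 and Atf3 2.30 ± 0.505 in DRG and 2.92 ± 1.23 in TG (-0.37 ± 0.27, adjusted p 0.253, 0.00926 with pan-neuronal centring).

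Glial and other non-neuronal markers were mostly higher in TG. Myelinating Schwann cell markers were higher in TG for 14 of 15 (camera adjusted p 1.74e-12, adjusted p = 0.246 with an estimated correlation). Mag, myelin-associated glycoprotein, had FPKM 1.62 ± 0.438 in DRG and 11.8 ± 3.62 in TG (-2.89 ± 0.24), and Prx, periaxin, 18.4 ± 3.67 in DRG and 105 ± 13.5 in TG (-2.52 ± 0.14). Satellite glia markers were 2 higher in DRG, 8 higher in TG and 2 not passing (1 in DRG and 10 in TG with pan-neuronal centring, camera adjusted p 0.0425, adjusted p = 0.525 with an estimated correlation). Gja1 had -1.91 ± 0.18. The list's adjusted p was 0.0511 without DRG replicate 1 and 0.0731 without TG replicate 1. Macrophage and leukocyte markers were 0 higher in DRG, 10 higher in TG and 4 not passing (0 in DRG and 14 in TG with pan-neuronal centring, camera adjusted p 0.00137, adjusted p = 0.415 with an estimated correlation). Cd163 had -1.86 ± 0.21. Endothelial and mural cell markers were 2 higher in DRG, 9 higher in TG and 4 not passing (0 in DRG and 13 in TG with pan-neuronal centring, camera adjusted p 0.0204, adjusted p = 0.268 with an estimated correlation). Kdr had -1.79 ± 0.12. Fibroblast and meningeal markers were 0 higher in DRG, 7 higher in TG and 7 not passing (0 in DRG and 10 in TG with pan-neuronal centring, camera adjusted p 0.0484, adjusted p = 0.607 with an estimated correlation), Pdgfra at -1.55 ± 0.13. The list's adjusted p was 0.0711 without DRG replicate 2, 0.0769 without TG replicate 1 and 0.0910 without TG replicate 2. With pan-neuronal centring the satellite glia, macrophage, endothelial and fibroblast lists lost their calls (adjusted p 0.101, 0.0598, 0.0957 and 0.617). Their differences toward TG grew, with medians of -0.55 before and -1.11 after, -0.91 before and -1.47 after, -0.50 before and -1.06 after and -0.78 before and -1.34 after.

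Transcripts typical of the pituitary and of central glia were higher in TG. All 6 tested pituitary markers, of 11 listed, were higher there (camera adjusted p 1.22e-04, adjusted p = 0.246 with an estimated correlation). Cga, the common subunit of the glycoprotein hormones, was at least 547-fold higher, at 0 ± 0 in DRG and 38.8 ± 26.0 in TG, and Gh, growth hormone, had 0.767 ± 0.381 in DRG and 375 ± 241 in TG (-8.87 ± 0.59, and -8.26 without TG replicate 3). Central oligodendrocyte and astrocyte markers were 1 higher in DRG, 6 higher in TG and 0 not passing (camera adjusted p 2.05e-05, adjusted p = 0.268 with an estimated correlation). Gfap, an astrocyte filament protein that some peripheral glia also make, had 0.183 ± 0.0379 in DRG and 30.6 ± 13.1 in TG (-7.37 ± 0.40). Mog, a protein of central myelin, was higher by 251-fold, with a counting interval from 85.7 to 1220.5, its fitted log2 fold change of -7.87 becoming -8.61 without DRG replicate 3. Neutrophil and bone marrow markers were higher in DRG for all 5 tested, of 9 listed (camera adjusted p 0.00154, adjusted p = 0.311 with an estimated correlation). S100a9 had 3.76 ± 0.42. Erythrocyte markers were also higher in DRG for all 5 (camera adjusted p 0.189, but 0.0265 without DRG replicate 3 and 0.0118 with pan-neuronal centring). Without DRG replicate 1, Hbb-bs, a beta-globin with near-identical copies and so uncertain, went from 2.18 ± 0.44 to 1.48.

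By edgeR's quasi-likelihood test, 8587 of 12922 tested genes (66.5%) differed between DRG and TG, 4305 higher in DRG and 4282 higher in TG. At least a 2-fold difference was reached by 1198 and 940 of them. All 3 libraries of 1 group lay above the 3 of the other for 9143 tested genes (70.8%, against 10% by chance). Pan-neuronal centring shifted the median gene by -0.56 and gave 1551 genes higher in DRG and 8386 higher in TG, with 554 genes called in the opposite direction. With a filter of FPKM 5, the calls of the potassium channels (0.0583), pan-neuronal genes (0.0558), satellite glia (0.0583), endothelial cells (0.733) and fibroblasts (0.107) ended, and the anterior Hox, cold and neutrophil lists kept under 3 members. Apart from Trpa1 and Atf3, whose libraries overlapped, adjusted p of the genes named for this comparison ran from 4.77e-09 for Hoxa9 to 0.0213 for Hoxd1 by edgeR's quasi-likelihood test, and all libraries of the higher group lay above those of the other.

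**Figure D2:**
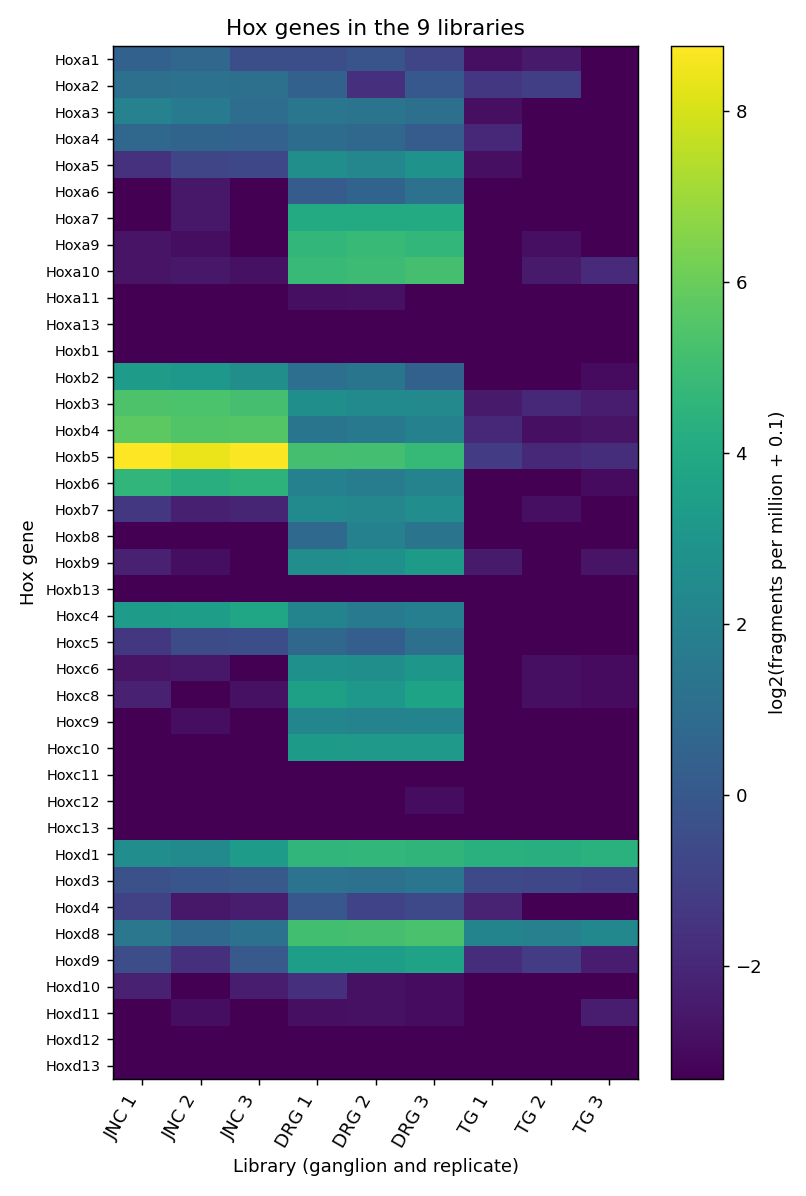
Hox genes in each library, as log2 of CPM plus 0.1, from dark (low) to yellow (high). Columns are the 9 libraries and lines the Hox genes of both lists by cluster and paralog number. Hoxb5 lay between 340 and 433 CPM in JNC, between 27.0 and 36.5 in DRG and at or under 0.324 in TG.

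The last pair of ganglia placed the vagal ganglia beside the trigeminal ganglia, the somatosensory ganglia of the head. JNC again carried the placodal genes, together with anterior Hox genes and the irritant channels, and TG higher levels of Trpm8 and of myelin, pituitary and central glia transcripts. With an estimated correlation camera called 2 lists, the placodal markers and the anterior Hox genes. P2rx2 had FPKM 93.1 ± 5.19 in JNC and 0.450 ± 0.270 in TG (log2 fold change 7.83 ± 0.20) and Hoxb5 217 ± 24.4 in JNC and 0.128 ± 0.0449 in TG (10.70 ± 0.19). Trpm8 had 3.70 ± 1.75 in JNC and 41.6 ± 6.04 in TG (-3.48 ± 0.26).

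Placodal vagal markers were higher in JNC for 16 of 17 and higher in TG for 1 (camera adjusted p 1.51e-36, adjusted p = 0.00417 with an estimated correlation). Vip had FPKM 18.0 ± 5.15 in JNC and 0.0834 ± 0.0255 in TG (7.66 ± 0.33) and Uts2b 35.8 ± 9.05 in JNC and 0.115 ± 0.0957 in TG (8.07 ± 0.36, and 9.01 without TG replicate 3). Visceral mediator receptors were 15 higher in JNC, 5 higher in TG and 6 not passing (camera adjusted p 1.47e-04, adjusted p = 0.0931 with an estimated correlation). Glp1r had 6.81 ± 0.28 and Gpr65 had 4.70 ± 0.14. P2X, serotonin, nicotinic and acid-sensing channels were 11 higher in JNC, 6 higher in TG and 2 not passing (camera adjusted p 1.76e-07, adjusted p = 0.0623 with an estimated correlation), Chrna3 at 164 ± 11.1 in JNC and 2.32 ± 0.524 in TG (6.14 ± 0.16) and Chrnb4 at 5.71 ± 0.14. Neuropeptides were 9 higher in JNC, 4 higher in TG and 2 not passing (7 in JNC and 4 in TG with pan-neuronal centring, camera adjusted p 0.00810, adjusted p = 0.248 with an estimated correlation). Cartpt had 4.87 ± 0.17. Nerve injury response genes were 12 higher in JNC, 4 higher in TG and 4 not passing (camera adjusted p 0.00214, adjusted p = 0.113 with an estimated correlation). Gch1, the first enzyme of tetrahydrobiopterin synthesis, had 3.17 ± 0.16, and Atf3 3.88 ± 0.822 in JNC and 2.97 ± 1.27 in TG (0.37 ± 0.26, adjusted p 0.227, and 0.0106 without TG replicate 3). Anterior Hox genes were higher in JNC for 6 of 7 and higher in TG for 1 (camera adjusted p 7.54e-15, adjusted p = 0.0399 with an estimated correlation). Hoxc4 was at least 317-fold higher, at 5.95 ± 1.30 in JNC and 0 ± 0 in TG. Of paralogs 6 to 13 only 2 could be tested. Hoxb6 was higher in JNC by 1826-fold, with a counting interval from 327 to 72163, its fitted 10.32 becoming 11.98 without TG replicate 3, and Hoxd8 was higher in TG (-1.04 ± 0.24).

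Nociceptor channels and peptides were 8 higher in JNC, 4 higher in TG and 3 not passing (4 in JNC and 4 in TG with pan-neuronal centring, camera adjusted p 0.148). Trpv1 had FPKM 19.0 ± 1.22 in JNC and 3.97 ± 0.319 in TG (2.26 ± 0.11), Trpa1 60.3 ± 6.40 in JNC and 13.2 ± 2.30 in TG (2.18 ± 0.12) and the ATP-gated channel subunit P2rx3 157 ± 6.67 in JNC and 49.9 ± 3.33 in TG (1.65 ± 0.08). Lower in JNC were Tac1 at 102 ± 21.9 in JNC and 170.4 ± 9.76 in TG (-0.75 ± 0.12), Calca at 247 ± 103 in JNC and 555 ± 50.02 in TG (-1.18 ± 0.23) and Prdm12 at 9.68 ± 3.66 in JNC and 35.9 ± 4.65 in TG (-1.90 ± 0.20). Neural crest somatosensory markers were 3 higher in JNC, 12 higher in TG and 4 not passing (camera adjusted p 0.198, but 0.0418 with pan-neuronal centring). Their largest difference ran against the list's name, with Cysltr2, a cysteinyl leukotriene receptor, at 105 ± 18.5 in JNC and 6.47 ± 1.07 in TG (4.01 ± 0.15). Mechanoreceptor and proprioceptor markers were 4 higher in JNC, 10 higher in TG and 1 not passing (camera adjusted p 0.234, but 0.0228 with pan-neuronal centring), with Th at 3.83 ± 0.13 and Calb1 at -3.03 ± 0.14. Cold-sensing neuron markers were 1 higher in JNC, 4 higher in TG and 1 not passing (camera adjusted p 0.0567, but 0.0126, 0.0333, 0.0466 and 0.0427 without JNC replicate 1 or 3 or TG replicate 1 or 3 and 0.00639 with pan-neuronal centring), with Kcnk9 at 3.08 ± 0.22 and Cdh8 at -2.60 ± 0.16. TRP channels were 7 higher in JNC, 6 higher in TG and 2 not passing (camera adjusted p 0.525). Trpc4 had 2.88 ± 0.13. Sodium channels were 7 higher in JNC, 6 higher in TG and 0 not passing (5 in JNC and 6 in TG with pan-neuronal centring, camera adjusted p 0.897). Scn1a had -1.92 ± 0.14. Potassium channels were 13 higher in JNC, 14 higher in TG and 4 not passing (9 in JNC and 13 in TG with pan-neuronal centring, camera adjusted p 0.164), with Kcnh5 at -4.29 ± 0.15 and the acid-sensitive two-pore channel Kcnk3 at 3.61 ± 0.12. Transcription factors were 8 higher in JNC, 7 higher in TG and 4 not passing (camera adjusted p 0.698, median log2 fold change 0.12, -0.01 after quantile normalization), with Meis2 at -3.03 ± 0.10 and Eya1 at 2.69 ± 0.11. Cytokine and neurotrophic factor receptors and ligands were 6 higher in JNC, 11 higher in TG and 9 not passing (camera adjusted p 0.265), with Ngfr, the low-affinity neurotrophin receptor, at 2.08 ± 0.09.

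Beside these neuron genes, all 15 myelinating Schwann cell markers were higher in TG (camera adjusted p 8.80e-15, adjusted p = 0.233 with an estimated correlation), Ugt8a at FPKM 8.47 ± 2.60 in JNC and 148 ± 22.8 in TG (-4.13 ± 0.20) and Mag at -3.49 ± 0.24. Satellite glia markers were 2 higher in JNC, 8 higher in TG and 2 not passing (camera adjusted p 0.0466, adjusted p = 0.578 with an estimated correlation, and 0.0516 without JNC replicate 1). Macrophage and leukocyte markers were 0 higher in JNC, 8 higher in TG and 6 not passing (camera adjusted p 0.0194, adjusted p = 0.578 with an estimated correlation). Mrc1 had -1.74 ± 0.15. Fibroblast and meningeal markers were 2 higher in JNC, 9 higher in TG and 3 not passing (camera adjusted p 0.00167, adjusted p = 0.428 with an estimated correlation). Ptgds, a prostaglandin synthase abundant in meninges, had 14.99 ± 2.78 in JNC and 848 ± 368 in TG (-5.83 ± 0.32). Pituitary markers were higher in TG for all 6 tested, of 11 listed (camera adjusted p 1.47e-04, adjusted p = 0.233 with an estimated correlation). Prl had 1.53 ± 0.585 in JNC and 1475 ± 1124 in TG (-9.95 ± 0.67, and -9.22 without TG replicate 3) and Gh had -9.61 ± 0.58 (-9.01 without it). Cga was higher by 1407-fold, with a counting interval from 252 to 55615, its fitted -10.01 becoming -11.97 without JNC replicate 2. Central oligodendrocyte and astrocyte markers were 1 higher in JNC, 6 higher in TG and 0 not passing (camera adjusted p 1.29e-05, adjusted p = 0.340 with an estimated correlation), Mobp at 0.0201 ± 0.0232 in JNC and 20.1 ± 9.42 in TG (-9.48 ± 0.56, and -10.86 without JNC replicate 2). Sympathetic neuron and chromaffin markers were 4 higher in JNC, 2 higher in TG and 1 not passing (camera adjusted p 0.00379, adjusted p = 0.233 with an estimated correlation). Ddc had 4.65 ± 0.14. Pan-neuronal genes were 10 higher in JNC, 6 higher in TG and 1 not passing (camera adjusted p 0.356). Uchl1 had 1.71 ± 0.09 and Nefh had -1.91 ± 0.16.

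By edgeR's quasi-likelihood test, 8890 of 13084 tested genes (67.9%) differed between JNC and TG, 4571 higher in JNC and 4319 higher in TG. At least a 2-fold difference was reached by 1811 and 1223 of them. Pan-neuronal centring gave 3246 higher in JNC and 3677 higher in TG. Among the largest were Cfd, the adipocyte serine protease adipsin, at least 309-fold higher in JNC at 16.3 ± 18.2 in JNC and 0 ± 0 in TG (fitted 11.28, and 9.85 without JNC replicate 1), and Klk6, a kallikrein protease, at least 185-fold higher in TG at 0 ± 0 in JNC and 7.65 ± 3.98 in TG. All 3 libraries of 1 group lay above the 3 of the other for 9366 tested genes (71.6%, against 10% by chance). With limma on log2(FPKM + 0.1), 6 lists lost their camera calls: the P2X to acid-sensing channels (adjusted p 0.0924), visceral mediator receptors (0.0562), neuropeptides (0.165), injury genes (0.0562), satellite glia (0.0837) and sympathetic markers (0.230). With a filter of FPKM 5 the satellite glia and macrophage lists did (0.0631 and 0.0733). Apart from Atf3, whose libraries overlapped, adjusted p of the genes named for this comparison ran from 1.20e-12 for Hoxb5 to 0.00210 for Hoxd8 by edgeR's quasi-likelihood test, and all libraries of the higher group lay above those of the other.

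**Figure D3:**
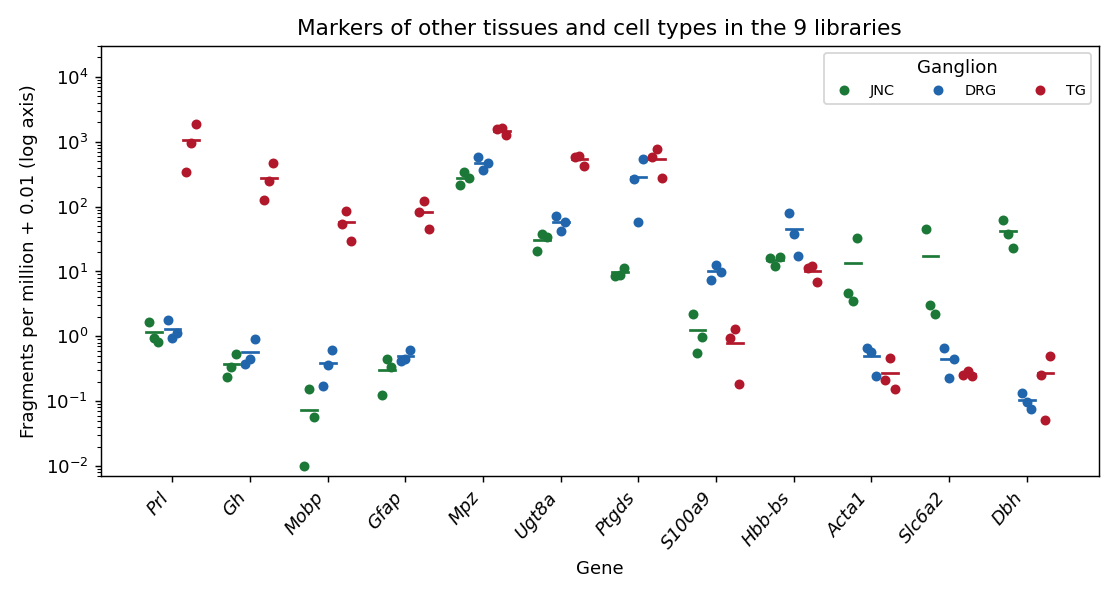
Markers of other tissues and cell types in each library, as CPM plus 0.01 on a log axis. Points are libraries, coloured by ganglion, and the short lines are means of n = 3. Prl ran from 342 to 1874 CPM in the TG libraries and was at or under 1.76 in the others, while Slc6a2 stood at 45.7 in JNC replicate 1 and at or under 3.07 elsewhere.

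The 2 comparisons that involve JNC together asked what distinguished vagal ganglia from both somatosensory ganglia. Higher in JNC than in both were 2017 of the 12694 genes tested in both tables, and lower than in both were 1717. With pan-neuronal centring the genes higher in JNC than in both DRG and TG numbered 2827 and the genes lower in JNC than in both DRG and TG 548. These are not counts at equal neuron content, as the median of the pan-neuronal genes then stood at 0.42 against DRG and 0.51 against TG. At least 2-fold differences against both were shown by 491 and 380 genes, and at least 8-fold differences by 91 and 11. Among those higher in both, Ltk, a receptor tyrosine kinase, had log2 fold changes of 7.70 against DRG and 8.95 against TG (8.69 against DRG without DRG replicate 3, and 12.00 and 8.26 against TG without TG replicate 1 and 3). Crhr2, a receptor for corticotropin-releasing hormone and urocortins, had 6.05 against DRG and 6.06 against TG, and Tmc3, a transmembrane channel-like gene, 5.95 against DRG and 6.66 against TG. Among those lower in both were Hcrtr2, an orexin receptor (-3.28 against DRG and -3.08 against TG, and -3.87 and -3.68 without JNC replicate 3), Kcnh5 (-2.95 against DRG and -4.29 against TG) and the neuronal pentraxin Nptx1 (-2.85 against DRG and -2.83 against TG). These were not the largest. Genes reaching FPKM 5 in DRG or TG were ranked by the smaller of their 2 differences. Ptgds of the fibroblast and meningeal list came first (-4.95 against DRG and -5.83 against TG). Igf2 of the same list and Pmp2 of the Schwann cell list also stood above Hcrtr2, Kcnh5 and Nptx1. Ltk, Crhr2, Tmc3, Hcrtr2 and Nptx1 were named after their values were seen. Lists of these sizes drawn independently would share 1056 and 880 genes. Both comparisons used the same JNC libraries, which by itself raises such an overlap. When both tables were refitted on the 12694 common genes the counts were 1959 and 1808. In 20 simulations of unchanged groups sharing the JNC libraries the means were 0.05 and 0.1 genes. No gene differed in these simulations, so hardly any could be called in either comparison. They cannot show how far sharing JNC raises an overlap where many genes differ. The 3 JNC libraries could not be split into parts of at least 2, so part of the excess may come from sharing them.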

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

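Limma on log2(FPKM + 1) was named in the design before the data were examined and run as an alternative because the tables held counts. DESeq2, the fit of all 9 libraries and leaving out libraries for single genes were chosen after the main results were seen. The numbers of genes differing between 2 ganglia stayed within 1.5 times the main counts under every alternative run except the 2-fold threshold, which left 1411 genes for JNC and DRG, 2138 for DRG and TG and 3034 for JNC and TG, and gave 491 and 380 for the genes higher in JNC than in both DRG and TG and the genes lower in JNC than in both DRG and TG. That threshold by construction keeps fewer genes. These totals do not say that the same genes were called. With pan-neuronal centring 8712 genes were called for JNC and DRG. Of the 5817 main calls there, 3721 kept their call and direction and 24 were called the other way. For DRG and TG 5833 of 8587 were kept and 554 turned, and for JNC and TG 6883 of 8890 were kept and 0 turned. Pan-neuronal centring also left 548 genes lower in JNC than in both DRG and TG, against 1717. That centring shifted the median gene by 0.51 for JNC and DRG and by -0.07 for JNC and TG. The shift toward JNC takes genes out of the lower call against DRG. Leaving out 1 library gave 4731 to 5657 genes for JNC and DRG, 7618 to 8487 for DRG and TG and 8303 to 8486 for JNC and TG. The overlaps ranged from 1676 to 2005 and from 1464 to 1738.

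Gene lists called by camera numbered 14, 17 and 13, and 2, 0 and 2 with an estimated correlation, where fry in limma called 19, 25 and 23. Limma on log2(FPKM + 0.1) left 8 for JNC and DRG and 7 for JNC and TG, and the cause was not tested. A filter of FPKM 5 left 9 for DRG and TG, with fewer genes tested. Adjusting p over the members of a list alone changed the count of members called in 4 lists for JNC and DRG (cold 2 and 3, injury 11 and 5, satellite glia 0 and 1, Schwann cells 0 and 13), in 0 for DRG and TG and in 2 for JNC and TG (neural crest 3 and 13, neutrophils 0 and 0).

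Of 3522 values of 187 gene results in the text under the alternatives, 3500 kept their side of the threshold and, where they passed it, their direction. Of the rest, 18 no longer passed, 2 newly passed and 2 reversed. Most of these genes were named for large differences past the threshold in these same data. Their stability was thus largely set by that choice and is no independent support. The reversed values were those of Hoxd1 of DRG and TG (-0.28) and Trpa1 of DRG and TG (-0.25) with pan-neuronal centring, which shifts every gene. With the replicate number as a replicate block, 5437, 8446 and 8917 genes were called, and the nociceptor list of JNC and DRG (adjusted p 0.0310) and the cold list of JNC and TG (0.0219) were gained. Correlations of libraries with the same number after removing group means ran from -0.110 to 0.199. With 3 libraries per group such values neither show nor exclude pairing, so whether the numbers pair the samples is not known. Deposited q-values were not in the tables, so that alternative was not run. Depth limited genes near 0 fragments, where folds are bounds or intervals.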

Other observations

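The tests on regrouped libraries, the comparison of Schwann cell with endothelial markers and the genes singled out in this part were chosen after the results were seen. The tests of pituitary and central tissue were written before theirs were seen. Htr3a and Htr3b, the subunits of the serotonin-gated channel, had FPKM 349 ± 25.4 in JNC and 41.0 ± 5.15 in DRG and 59.6 ± 7.09 in JNC and 7.46 ± 0.629 in DRG, with edgeR quasi-likelihood log2 fold changes of 3.10 ± 0.10 and 3.01 ± 0.11. Other serotonin receptor genes on the visceral list were lower in JNC than in DRG, with Htr1a at -1.98 ± 0.18, Htr2a at -1.83 ± 0.17 and Htr4 at -2.53 ± 0.16. So was Htr1b (adjusted p 0.00279, 0.0693 with pan-neuronal centring). Cckar, a cholecystokinin receptor of satiety, had 86.4 ± 6.86 in JNC and 16.3 ± 1.52 in DRG (2.41 ± 0.09), and Npy2r, a receptor of peptide YY, 28.2 ± 2.20 in JNC and 11.8 ± 1.44 in DRG (1.27 ± 0.09). Against TG, Htr3a, Htr3b, Cckar and Npy2r had 2.83 ± 0.10, 2.71 ± 0.11, 2.93 ± 0.11 and 2.82 ± 0.12. Kcnk18, a two-pore potassium channel, was high in JNC and TG and lower in DRG, with 1.59 ± 0.09 for JNC and DRG and -1.25 ± 0.11 for DRG and TG. Adcyap1, encoding the peptide PACAP, had 0.49 ± 0.08 and 1.34 ± 0.08 in JNC against DRG and TG.

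Myl1, a fast muscle myosin light chain, stood at 32.3, 27.3 and 33.0 CPM in JNC replicates 1 to 3, while the muscle genes Acta1 (4.66, 3.50 and 32.8) and Atp2a1 (0.920, 1.24 and 38.5) rose in replicate 3 alone, so Myl1 did not follow them. Among sympathetic genes Slc6a2 stood at 45.7, 3.07 and 2.20 CPM and Npy at 4.66, 0.0365 and 0.0468, high in replicate 1 only, whereas Dbh (63.2, 38.2 and 22.7) and Ddc (55.7, 57.0 and 51.1) were present in all. Cfd stood at 29.7, 4.34 and 4.49. Cck in TG rested on replicate 2 (0.810, 8.44 and 0.433 CPM), and Alas2 in DRG on replicate 1 (19.5, 4.05 and 3.00).

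The remaining lists were as follows. Between JNC and DRG they were macrophages (1 of 10 higher in JNC and 0 in DRG, 7 in JNC and 0 in DRG with pan-neuronal centring, camera adjusted p 0.670), erythrocytes (0 of 5 higher in JNC and 4 in DRG, camera adjusted p 0.400), endothelial cells (3 of 13 higher in JNC and 2 in DRG, 10 in JNC and 1 in DRG with pan-neuronal centring, camera adjusted p 0.860), muscle (1 of 1 higher in JNC and 0 in DRG), central glia (1 of 3 higher in JNC and 2 in DRG, camera adjusted p 0.820, median log2 fold change -0.47, 0.01 after pan-neuronal centring), pituitary (0 of 2 higher in JNC and 1 in DRG) and thyroid and airway (1 of 4 higher in JNC and 1 in DRG, camera adjusted p 0.670, median log2 fold change -0.36, 0.12 after pan-neuronal centring). The erythrocyte list had camera adjusted p 7.49e-06 with pan-neuronal centring. Between DRG and TG they were cytokine and neurotrophic genes (12 of 27 higher in DRG and 8 in TG, 8 in DRG and 17 in TG with pan-neuronal centring, camera adjusted p 0.189, median log2 fold change 0.15, -0.41 after pan-neuronal centring), immediate early genes (3 of 12 higher in DRG and 5 in TG, 1 in DRG and 8 in TG with pan-neuronal centring, camera adjusted p 0.270), sympathetic markers (2 of 4 higher in DRG and 1 in TG, camera adjusted p 0.0847, 0.0315 without DRG replicate 3, median log2 fold change 0.12, -0.45 after pan-neuronal centring), thyroid and airway (3 of 4 higher in DRG and 0 in TG, camera adjusted p 0.0847, 0.0391 with limma on log2(FPKM + 0.1) and 0.0332 with pan-neuronal centring) and cartilage (2 of 3 higher in DRG and 0 in TG, camera adjusted p 0.241), and no muscle gene could be tested. Between JNC and TG they were immediate early genes (7 of 13 higher in JNC and 3 in TG, 5 in JNC and 3 in TG with pan-neuronal centring, camera adjusted p 0.995), neutrophils (1 of 2 higher in JNC and 0 in TG), erythrocytes (3 of 5 higher in JNC and 0 in TG, camera adjusted p 0.698), endothelial cells (2 of 15 higher in JNC and 7 in TG, camera adjusted p 0.114, 0.0341 without JNC replicate 1), muscle (2 of 2 higher in JNC and 0 in TG), thyroid and airway (2 of 4 higher in JNC and 1 in TG, camera adjusted p 0.356) and cartilage (0 of 1 higher in JNC and 1 in TG). Egr2, a transcription factor of myelinating glia, led the immediate early genes in TG (-2.66 ± 0.18 against DRG and -2.82 ± 0.15 against JNC).

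Hormone transcripts were high in TG, which lies close to the pituitary in the skull. If pituitary tissue was carried along at dissection, further pituitary genes outside the list would be higher too. Their median log2 ratio of TG to DRG was 2.80 (bootstrap interval over 8 genes from 1.20 to 3.97), with 7 of 8 higher in TG, among them Pitx1 (0 and 59 fragments in DRG and TG) and Six6 (7 and 125), while Trhr was lower. A fragment was added to each group, and the other genes higher in TG held fewer fragments. They were Lhx4 (1 and 4), Nr5a1 (1 and 7), Hesx1 (0 and 8), Lhx3 (2 and 18) and Gnrhr (1 and 33). The lower end of the interval is the ratio of Lhx4. The TG fragments of Lhx4 and of Nr5a1 were all in TG replicate 3. The median met what carried tissue needs, though on few fragments for most of the genes, so pituitary tissue may account for the hormone transcripts. Hormone expression within the ganglion itself was not tested and stays open.

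Central glial transcripts, such as Gfap and Mobp, were also high in TG. If central tissue that holds neuron cell bodies had been carried along, markers of central neurons would rise, but their median log2 ratio of TG to DRG was 0.49 (bootstrap interval over 12 genes from -0.18 to 2.04, 8 of 12 higher in TG). The interval includes 0, so such tissue could be neither excluded nor shown. Some of these markers were abundant in DRG itself, such as Slc17a7 (6219 fragments in DRG and 4542 in TG) and Zic1 (657 and 636). They can hold the median near 0 whether or not central tissue was present. Others were near 0 in DRG and rose on few fragments, such as Gabra6 (0 and 13) and Neurod6 (0 and 6). The central part of the nerve root, which holds central glia without neuron cell bodies, stays open as a source and was not tested.

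Myelin genes were higher in TG than in DRG. Of 17 pan-neuronal genes 11 were higher in DRG and 2 in TG (camera adjusted p 0.0136, adjusted p = 0.415 with an estimated correlation). A lower share of neurons alone would raise the markers of every other cell type alike. The mean log2 ratio of TG to DRG was 1.91 for Schwann cell, 0.61 for satellite glia, 1.00 for macrophage, 0.70 for endothelial and 0.90 for fibroblast markers, and the Schwann cell list exceeded the endothelial list by 1.22 (p 5.90e-04 by 100000 permutations of genes). Permuting genes treats list members as independent, while the correlation estimated for the Schwann cell list was 0.70, so this p is probably too small. It measures spread between genes and not between libraries. In these libraries the Schwann cell mean exceeded that of each other list. This cannot decide whether a lower share of neurons was the whole cause. Oligodendrocytes also make some of the Schwann cell list, such as Mag, which stood at 28.2, 37.8 and 19.3 CPM in TG replicates 1 to 3, beside 54.5, 86.7 and 29.6 for the central marker Mobp and 452, 583 and 495 for Prx of peripheral myelin. Central myelin and more Schwann cells or more myelin per cell in TG were not tested, and these and the neuron share stay open.

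Regrouping the libraries gave a check on all counts. Of the 10 splits of the 6 libraries of each pair, 1, the real one, gave as many genes by edgeR's quasi-likelihood test (5817, 8587 and 8890, against at most 0 in any other split). It was also the 1 split with as many gene lists by camera (14, 17 and 13), but the highest other splits gave 12, 16 and 8. With 10 splits no share under 0.05 can be reached. Of 50 groupings of the 9 libraries, 1, the real one, gave as many genes higher (1959, highest other 120) and lower (1808, highest other 73) in JNC than in both. Each other split or grouping put libraries of different ganglia together, and these correlate less than libraries of 1 ganglion. The counts thus followed the ganglion labels. This cannot tell the ganglion from anything else that differed between the groups, such as a batch or shared animals.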
